A study of Mus musculus with 9 samples.

How the data were processed

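RNA from cells of the brain ventricular zone of newborn mice was measured on 9 Affymetrix Mouse Gene ST 1.0 microarrays. The ventricular zone is the layer that lines the cerebral ventricles and holds the radial glia and other progenitors. Per the labels' protocols, the zone was dissected from C57BL/Ka pups, the cells were not cultured, and total RNA was taken up in Trizol and column-purified. Per the same protocols, RNA was amplified with a NuGEN whole-transcript kit, and biotin-labelled cDNA was hybridized. The groups are the genotypes that the labels give: Prdm16+/+ (WT), Prdm16LacZ/+ (HET) and Prdm16LacZ/LacZ (KO), with 3 arrays each. Nothing in the labels says that the arrays of a group came from separate animals or litters, so the p-values below measure only the spread between these arrays, which may be technical.

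The authors deposited log2 values for 28940 probe sets, with no missing value. The submitters' processing notes name RMA, affy and limma, without versions or order; RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The annotation used at that step is not given in the sources used here. Array medians lay between 5.80 and 5.92 and lower quartiles between 4.53 and 4.68 on the log2 scale, as the table holds it. Detection calls were not used here, so a low value could be background as well as transcript.

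Probe sets were named from the annotation supplied with the array, in which 21789 probe sets had 1 gene symbol, 1621 had several and 5530 were not listed. Of the probe sets with 1 symbol, 21698 had a gene ID in the GRCm38.p6 gene table, and 0 symbols needed updating through it. That table served only for names and for the order of neighbouring genes, and no coordinates are given because the files name no genome build. Probe sets with several symbols or none were left out of the main tests. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays was taken, which left 19938 genes.

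Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) on the deposited log2 values, without further normalization or filter. All 9 arrays entered 1 fit with a mean per genotype, so that the genotypes shared 1 estimate of the spread. The p-values were adjusted over all 19938 genes with the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. The contrasts were KO against WT, HET against WT, KO against HET, KO against the mean of WT and HET, the slope on the number of wild-type alleles (0, 1 or 2), and HET against the midpoint of WT and KO. The correlation of the KO and HET changes was set against 100 simulations of unchanged groups that shared the WT arrays.

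The 25 gene lists, fixed from textbook knowledge, were tested with camera, which asks whether a list shifts relative to the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with a correlation estimated per list and fry, which asks whether the members move on balance one way, were run as alternatives. The lists covered cell types (radial glia and neural stem cells, cortical intermediate progenitors, ventral forebrain progenitors and olfactory neuroblasts, postmitotic neurons, astrocytes, oligodendrocyte lineage, ependymal cells and motile cilia, choroid plexus, microglia and macrophages, endothelial cells and pericytes, red blood cells, meninges and fibroblasts, and tissue of the midbrain, hindbrain and thalamus). They also covered the cell cycle, cell cycle inhibitors and p53 targets, oxidative stress defence, oxidative phosphorylation, the brown adipocyte programme, PRDM16 relatives and partners, growth factors and receptors with HGF, TGF-beta and BMP signalling, Notch signalling, Wnt signalling, immediate early genes and sex-linked genes.

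The samples, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule took Prdm16, Hgf and Met, and for each pairwise comparison the 10 largest rises and 10 largest falls among called genes whose groups did not overlap. Where fewer than 20 passed, genes with the smallest unadjusted p filled up to 20 and are named as not passing. Of each list it took the up to 3 members with the smallest unadjusted p in KO against WT, and it passed over predicted and clone genes. Hgf and the oxidative stress list were included because the study behind these arrays is known to have followed them up, so their direction here is not independent evidence.

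Alternatives were the replicate number as a block, only the arrays of the groups compared, eBayes with trend and robust settings, array weights, the dimmest 1 in 3 genes left out, every probe set tested, the mean of a gene's probe sets, quantile normalization, median centring, an adjusted p under 0.10, a change of at least 1.5-fold, sex-linked genes left out, and each array left out in turn. Added after seeing the data were the Xist level as a covariate and a fit without HET replicate 1 and KO replicate 2.

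The tests were tried on simulated arrays with the real means of the 19938 genes, over 10 runs with 200 changed genes each. The spread of each simulated gene was drawn from the distribution of spreads that limma fitted. It was the same in all genotypes, which the real spreads were not, so the rates below are only a guide. In KO against WT they recovered 52% of changes of 0.5 on the log2 scale and 95.6% of changes of 1, and 4.16% of the calls were of unchanged genes. In HET against WT they recovered 39.6% of changes of 0.5 and 94.4% of changes of 1. These rates hold where 200 genes change, since the adjustment is stricter where fewer do. In the real HET against WT, Ccdc190 at -0.57 (SE 0.091) had an unadjusted limma p of 7.8e-05 and an adjusted p of 0.99. The simulated rates thus do not say how large a change the real HET comparison could miss. The list step found a list shifted by -0.5 in 10 of 10 runs and called 1 of 240 unshifted lists. The simulated genes varied independently; regrouped real arrays called up to 4, 5 and 6 lists in the 3 pairwise comparisons, which is more than this rate gives. The number of arrays limits the precision: the median standard error of a pairwise log2 change was 0.104.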

Results

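Prdm16 encodes a zinc finger transcription regulator of stem cells and of brown fat. The arrays compare newborn ventricular zone cells with 2, 1 or 0 wild-type alleles of the gene, 3 arrays per genotype, and ask which transcripts depend on it. All arrays held values of similar range. Arrays of a genotype correlated at r between 0.989 and 0.996 across probe sets, and arrays of different genotypes between 0.988 and 0.995. These ranges overlap, so they do not set the genotypes apart. Probe sets are not independent replicates. The WT arrays varied least: the median SD of a gene was 0.077 in WT, 0.117 in HET and 0.130 in KO on the log2 scale. HET replicate 1 and KO replicate 2 received the lowest array weights, 0.547 and 0.364.

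Prdm16 itself was measured at 7.62, 7.57 and 7.23 in the WT arrays, 6.995, 7.34 and 6.998 in the HET arrays, and 5.69, 6.41 and 6.17 in the KO arrays. It fell 2.61-fold in KO against WT (log2 change -1.38, SE 0.18, limma with Benjamini-Hochberg adjusted p = 0.010, n = 3 per genotype). The HET mean lay between, with a log2 change of -0.36 (SE 0.18) against WT that did not pass the test. Each KO array lay below every WT and HET array, while WT replicate 3 lay below HET replicate 2. The position of the probes relative to the LacZ insertion is not known here, so the value may not check the disrupted part of the gene. The KO against WT call was lost without WT replicate 1 or WT replicate 2 (adjusted p = 0.076 or 0.069) and with only the WT and KO arrays in the fit (0.080).

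**Figure D1:**
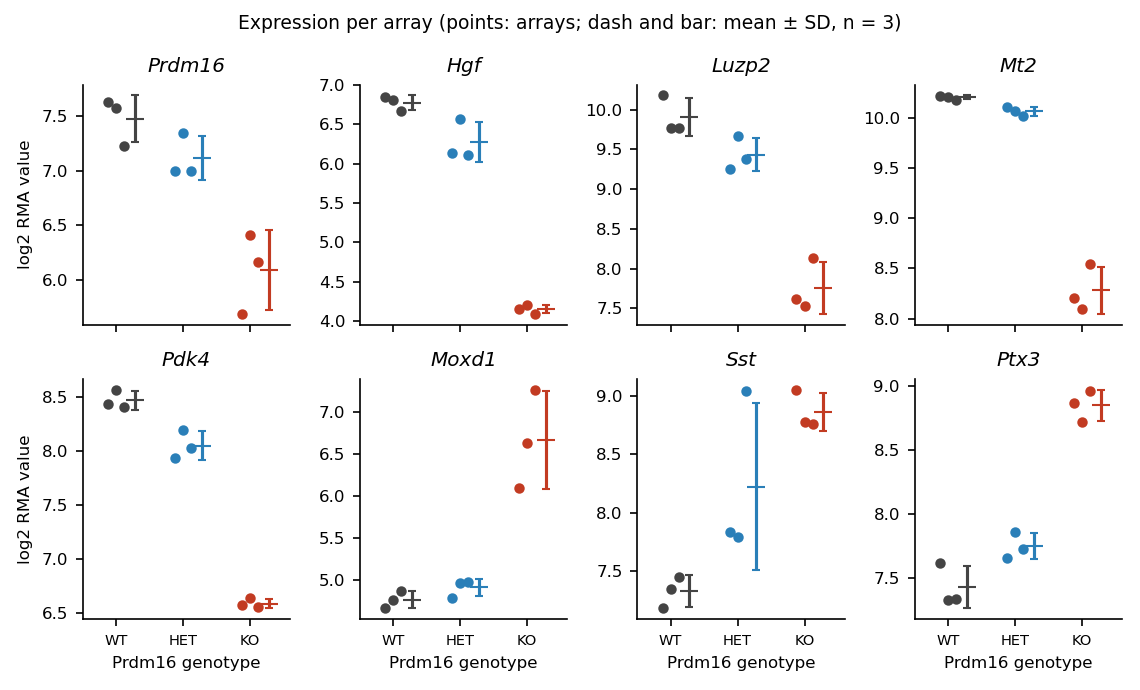
Log2 RMA values of 8 genes in each array, by Prdm16 genotype (points: arrays; dash and bar: mean ± SD, n = 3); the vertical axes differ between panels and do not start at 0. Hgf lies at a mean of 6.78 in WT, 6.27 in HET and 4.15 in KO, while 1 HET array, replicate 3, lies at 9.04 for Sst, within the range of the KO arrays.

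The comparison of KO with WT asks what changes when both alleles are lost. Hgf, the ligand of the receptor Met, fell the most, 6.19-fold (log2 change -2.63, SE 0.12, adjusted p = 6.4e-06 by limma with Benjamini-Hochberg, n = 3). Luzp2 fell 4.43-fold, Mt2, a metal-binding metallothionein, 3.78-fold, and Pdk4, the kinase that restrains pyruvate dehydrogenase, 3.67-fold. Among rising genes, Moxd1, a copper-dependent monooxygenase, rose 3.73-fold, and Sst, the neuropeptide somatostatin, 2.90-fold. Over all genes, 90 changed, 33 upward and 57 downward, and 12 and 23 of these by at least 2-fold.

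The falls reached several kinds of genes. Crym, a thyroid hormone binding protein, changed by -1.66 on the log2 scale (SE 0.21), and Capsl by -1.49 (SE 0.22). Ogn, a small proteoglycan, changed by -1.37 (SE 0.19), and Papss2, which makes the sulfate donor for proteoglycans, by -1.31 (SE 0.11). Cacna2d1, an auxiliary subunit of calcium channels, changed by -1.28 (SE 0.23). The metallothionein Mt1 fell with Mt2 (log2 change -0.76, SE 0.084) and was named after its values were seen. The KO mean of Hgf, 4.15, lay below the lower quartile of every array. Its receptor Met lay near 3.73 in KO and 3.75 in WT, also below the lower quartile of every array, and did not pass the test. At this level a change in Met might not be seen.

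The rises included secreted and neuronal genes. Ptx3, a pentraxin, rose by 1.42 on the log2 scale (SE 0.10), Gatm, an enzyme of creatine synthesis, by 1.40 (SE 0.16), and Ano1, a calcium-activated chloride channel, by 1.37 (SE 0.19). Pdzrn3, a ubiquitin ligase, rose by 1.35 (SE 0.13), the neuropeptide Npy by 1.27 (SE 0.19) and Has2, a hyaluronan synthase, by 1.18 (SE 0.10). Scrg1 rose by 1.14 (SE 0.19) and Sv2c, a synaptic vesicle glycoprotein, by 1.09 (SE 0.14). Sst had the weakest support of these, with an adjusted p of 0.047 by limma with Benjamini-Hochberg.

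All 90 calls had groups that did not overlap. Over all genes 1989 (9.98%) did so, where chance gives 10% for 3 against 3. Of the 19938 genes, 1227 had an unadjusted p under 0.05, more than the share of 0.05 that chance gives. The count was 23, 27 or 43 without WT replicate 1, 2 or 3, 59 without HET replicate 2, and 48, 54 or 41 without KO replicate 1, 2 or 3. It was 33 with only the WT and KO arrays in the fit, 151 with array weights, and 50 without HET replicate 1 and KO replicate 2.

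Single arrays also decided some calls of named genes; the highest adjusted p over all settings follows each gene. Without WT replicate 1 the calls of Moxd1 (0.080), Mgst1 (0.078), Ogn (0.12), Apoe (0.063), Htra1 (0.058), Gria1 (0.064) and Nid1 (0.076) were lost, and of these all but Moxd1 and Mgst1 were also lost without WT replicate 2. Ano1 (0.13) was lost without WT replicate 1 or 3 or KO replicate 3, Npy (0.14) without any 1 WT array or KO replicate 3, and Sv2c (0.076) without WT replicate 1 or 2 or KO replicate 2. Clu (0.093) was lost without WT replicate 1 or 2 or KO replicate 2 or 3, Capsl (0.13) without WT replicate 1 or 2, HET replicate 2 or KO replicate 1 or 3, and Lifr (0.13) without WT replicate 2 or 3, HET replicate 2 or KO replicate 1 or 3. Aqp4 (0.17) was lost without any 1 array but HET replicate 2 or KO replicate 2, Scrg1 (0.21) without any 1 but KO replicate 2 or 3, Sst (0.26) without any 1 but HET replicate 3, and Cacna2d1 (0.24) without any 1 of the 9. Gatm (0.062) and Crym (0.099) lost the call with only the WT and KO arrays in the fit, and Crym also without HET replicate 1 and KO replicate 2 together.

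Gene lists were tested for a shift relative to the other genes. In KO against WT, 4 of the 25 lists shifted by camera, all downward: astrocytes, ependymal cells and motile cilia, radial glia and neural stem cells, and oxidative stress defence. None held with an estimated correlation, and fry called 2, astrocytes (adjusted p = 0.040) and cilia (adjusted p = 0.037).

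Of 15 measured astrocyte genes, 3 fell over all genes and 8 when adjusted over the list alone, with a median log2 change of -0.31 (camera adjusted p = 1.0e-08; adjusted p = 0.13 with an estimated correlation). The 3 were Clu, a secreted chaperone (-1.05, SE 0.14), Aqp4, a water channel (-1.02, SE 0.17), and Apoe, a lipid carrier (-0.86, SE 0.11). Gja1, a gap junction protein, lay at -1.03 (SE 0.21) and did not pass over all genes. Gfap lay at -0.31 and did not pass, and 5 members lay above 0, among them Aldh1l1 at 0.21 (SE 0.12).

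The 33 genes of ependymal cells and motile cilia lay lower in 30 cases, with a median log2 change of -0.20 (camera adjusted p = 3.3e-16; adjusted p = 0.069 with an estimated correlation). None passed over all genes and 14 fell when adjusted over the list alone; 17 had an unadjusted p under 0.05. Enkur, a sperm tail and cilia protein, lay at -1.18 (SE 0.22), Rsph4a, a radial spoke protein, at -0.96 (SE 0.19) and Ak7, an adenylate kinase, at -0.53 (SE 0.12). Foxj1, the regulator of motile cilia, lay at -0.11 (SE 0.082).

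The radial glia list shifted by less, with a median of -0.08 over 26 genes (camera adjusted p = 0.020; adjusted p = 0.63 with an estimated correlation). None of its members passed over all genes or when adjusted over the list alone by limma, while 4 had an unadjusted p under 0.05. Prom1 lay at -0.57 (SE 0.16), Lhx2 at -0.42 (SE 0.12) and Ptprz1 at -0.30 (SE 0.099), and Sox2 at 0.22 (SE 0.11). Oxidative stress defence had a median of -0.06 over 33 genes (camera adjusted p = 0.013; adjusted p = 0.56 with an estimated correlation). Its 1 call over all genes, and 1 adjusted over the list alone, was Mgst1, a membrane glutathione transferase, which fell by 0.99 on the log2 scale (SE 0.12). Nfe2l2, a regulator of antioxidant genes, lay at -0.44 (SE 0.12) and Gsr, glutathione reductase, at -0.24 (SE 0.075), and neither passed. Both of these list calls were lost without WT replicate 1 (adjusted p = 0.13 and 0.090), KO replicate 1 (0.12 and 0.086), KO replicate 2 (0.067 and 0.081) or HET replicate 1 and KO replicate 2 together (0.083 and 0.17). The oxidative stress call was also lost with the dimmest 1 in 3 genes left out (adjusted p = 0.059).

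**Figure D2:**
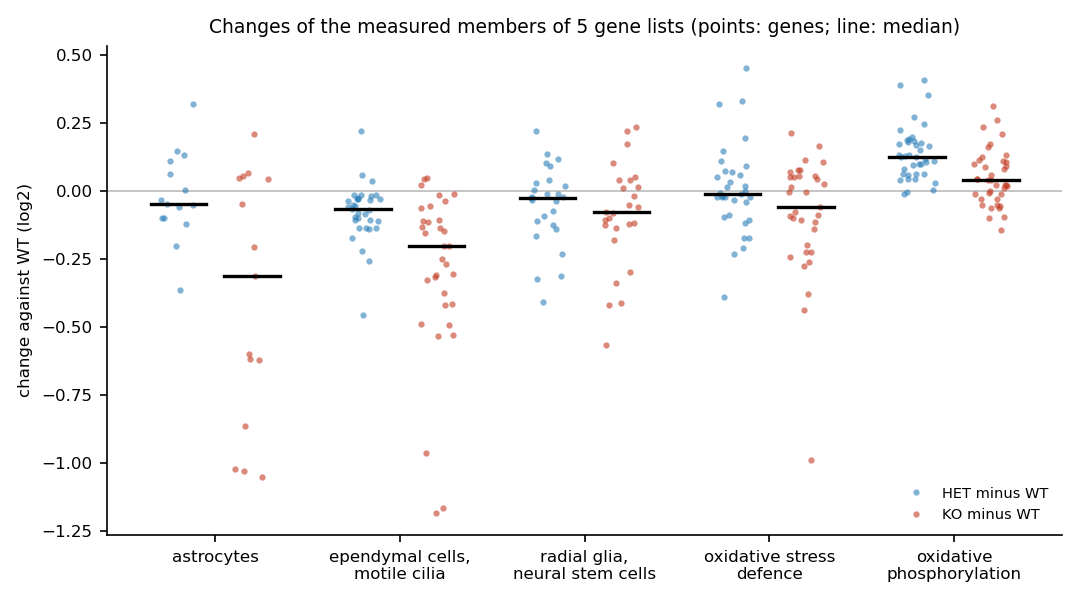
Log2 changes against WT of the measured genes of 5 lists, in HET and in KO (points: genes; line: median). Astrocyte and cilia medians lie at -0.31 and -0.20 in KO and at -0.05 and -0.07 in HET, and the oxidative phosphorylation median lies at 0.12 in HET and 0.04 in KO.

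The other 21 lists did not pass in KO against WT. Among neuronal lists, ventral forebrain progenitors had a median of 0.06 (camera adjusted p = 0.097), with the interneuron regulator Lhx6 at 0.72 (SE 0.18), Gad1 at 0.24 and Sp9 at 0.26. Lhx6 was the 1 gene of that list that rose when adjusted over the list alone, against 0 over all genes. Cortical intermediate progenitors (adjusted p = 0.12) had Neurog1 at -0.31, Eomes at -0.32 and Neurod4 at -0.15. Postmitotic neurons (0.85) had 1 member that rose and 1 that fell when adjusted over the list alone, the axonal filament gene Nefm at 0.44 (SE 0.11) and the cortical regulator Tbr1 at -0.66 (SE 0.13), with Neurod6 at 0.28. None of these 3 lists had a call over all genes.

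Lists of other cell types did not pass either. Choroid plexus (adjusted p = 0.77) held 1 rising gene, the clotting factor F5 (log2 change 0.89, SE 0.10, limma adjusted p = 0.0051), over all genes and over the list alone, from a WT mean of 4.42 that lay below the lower quartile of every array; its median of -0.02 and mean of 0.04 differed in sign, and Calml4 and Otx2 lay at 0.19 and 0.26. Meninges and fibroblasts (0.055) held 1 falling gene both ways, Ogn, with Pdgfra at 0.27 and Lum at -0.18. The adjusted p was 0.97 for the oligodendrocyte lineage (Cnp -0.43, Olig1 0.16) and 0.22 for microglia and macrophages (Cd68 0.26, Laptm5 0.18, Mrc1 0.21). It was 0.64 for endothelial cells and pericytes (Slco1a4 -0.27, Pdgfrb -0.29, Pecam1 0.28). It was 0.52 for red blood cells, of which 7 of 16 genes were measured (Alas2 -0.19, Hbb-y -0.09, Epb42 -0.04), and 0.86 for midbrain, hindbrain and thalamus (Prox1 0.30, Hoxb3 -0.11). None of these named values but F5 and Ogn passed the test.

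Cell cycle genes had a median of 0.06 (adjusted p = 0.38; Aurkb 0.31, Plk1 0.21, Cdc6 0.25), and cell cycle inhibitors and p53 targets 0.01 (0.85; Cdkn1c 0.24, Cdkn2b -0.22, Gadd45a 0.22). The growth factor list (0.85) held Hgf, which fell, and Lifr, the receptor of leukemia inhibitory factor, which rose by 0.93 on the log2 scale (SE 0.14, limma adjusted p = 0.018), over all genes and over the list alone; Egfr lay at 0.29. Its median of 0.01 and mean of -0.07 differed in sign. The brown adipocyte programme, which PRDM16 drives in fat, had an adjusted p of 0.85 (Ppargc1a -0.38, Dio2 -0.23, Elovl3 0.18), and PRDM16 relatives and partners 0.97 (Smad3 0.23, Prdm13 -0.21, Ctbp2 -0.10).

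Signalling lists did not pass: TGF-beta and BMP (adjusted p = 0.22; Bmp7 -0.27, Bmp6 -0.31, Bmpr1b 0.36), Notch (0.97; Dll1 0.20, Notch2 -0.24, Heyl -0.11) and Wnt (0.21; Wnt2b -0.35, Ccnd1 -0.28). Tnfrsf19, at -0.47 (SE 0.11), was the 1 Wnt gene that fell when adjusted over the list alone, against 0 over all genes. Oxidative phosphorylation (0.21; Atp5d 0.31, Cox5a 0.24, Ndufb8 0.26) and immediate early genes (0.21; Ccn1 -0.21, Ier3 0.27, Klf4 0.19) did not pass. Sex-linked genes had an adjusted p of 0.58, with Uty at -1.44 (SE 0.86), Kdm5d at -1.68 and Eif2s3y at -1.92; these differed between arrays of 1 genotype.

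Of these 21 lists, 5 passed by camera in some other setting. The meninges and fibroblasts list passed downward with array weights (adjusted p = 0.011), with the dimmest 1 in 3 genes left out (0.046), without WT replicate 2 (0.028), without KO replicate 2 (0.0064) and without HET replicate 1 and KO replicate 2 (0.0083). The ventral forebrain list passed upward without WT replicate 3 (adjusted p = 0.031) and without HET replicate 1 and KO replicate 2 (0.045), and oxidative phosphorylation upward without KO replicate 2 (0.0011) and without the same HET and KO arrays (0.00035). The cell cycle list passed upward without KO replicate 1 (adjusted p = 0.0025) but downward without KO replicate 3 (0.0044), where cortical intermediate progenitors also passed downward (0.027).

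The comparison of HET with WT asks whether the loss of 1 allele changes expression. No gene passed by limma with Benjamini-Hochberg in any setting run, and the smallest adjusted p was 0.99. Of the 19938 genes, 808 had an unadjusted p under 0.05, fewer than the share of 0.05 that chance gives. The gene with the smallest unadjusted p was Ccdc190, at -0.57 on the log2 scale (SE 0.091), followed by Fam171b at -0.41 and H2-M10.4 at -0.49. Hgf lay at -0.50 (SE 0.12), Pdk4 at -0.42 (SE 0.087) and Plagl1, an imprinted zinc finger gene, at -0.50 (SE 0.11). Veph1 lay at 0.55 (SE 0.12) and the glutamate receptor gene Gria1 at 0.41 (SE 0.097).

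The remaining named genes of this comparison also did not pass. Below WT lay Phc3 (-0.51), Tctex1d2 (-0.41), Tmem243 (-0.34), Ccdc136 (-0.33) and Diaph3 (-0.37). Above WT lay Magee1 (0.67), Cacng4 (0.52), Dner (0.50), Bod1 (0.38), Prkar1a (0.38), Ube2j2 (0.35) and Gfer (0.34).

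By camera, 2 lists shifted in HET. Cilia genes lay lower in 30 of 33 cases (median -0.07, adjusted p = 0.0091; adjusted p = 0.80 with an estimated correlation). Oxidative phosphorylation genes lay higher in 37 of 39 (median 0.12, adjusted p = 8.9e-07; adjusted p = 0.85 with an estimated correlation). No member of these lists passed over all genes or when adjusted over the list alone, with 1 cilia gene and 5 oxidative phosphorylation genes at an unadjusted p under 0.05, and fry called 0 lists. Of the growth factor list, 1 gene, Hgf, fell when adjusted over the list alone. The cilia call was lost without HET replicate 3 (adjusted p = 0.45) or WT replicate 1 (0.17), which left 1 list each, and 4 lists passed without WT replicate 3 or HET replicate 2. Radial glia joined without WT replicate 3 (0.033, downward) or HET replicate 2 (0.0023, downward), immediate early genes without WT replicate 3 (0.015, upward), cell cycle without HET replicate 2 (0.0030, downward) and postmitotic neurons without HET replicate 1 (0.0015, upward). The cilia call was also lost with quantile normalization (adjusted p = 0.075), where radial glia, cell cycle, oxidative phosphorylation and immediate early genes passed.

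**Figure D3:**
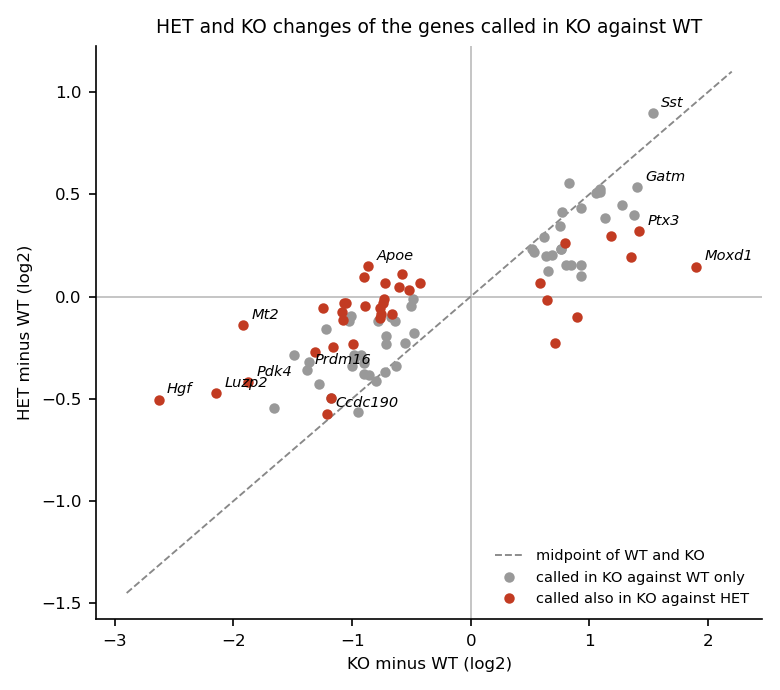
Log2 changes against WT in HET (vertical) and KO (horizontal) of the 90 genes called in KO against WT (points: genes; red: 37 genes called also in KO against HET; dashed line: the midpoint of WT and KO). For 80 of the genes HET lies on the same side of WT as KO, by a median of 22.5% of the KO change.

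The 90 genes called in KO placed HET between WT and KO more often than not: 80 lay on the KO side of WT and 10 on the other, with a median of 22.5% of the KO change (quartiles 9.67% and 36.7%). Both changes share the WT arrays. In 100 simulations with HET unchanged, 54.0% of called genes (41.2% to 68.2%) lay on the KO side, against 88.9% observed. The simulated genes varied independently, which real genes do not, so the simulated range is too narrow.

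Across all genes the KO and HET changes correlated at Pearson r = 0.42 and Spearman rho = 0.41. Simulated unchanged groups sharing the WT arrays gave r = 0.50 (0.45 to 0.54). The covariance was 0.00848 against 0.00701 simulated, a difference of 0.00147. The simulation gave all genotypes the same spread of a gene. The real median SD was lower in WT, 0.077, than in HET, 0.117, and KO, 0.130. With less spread in the shared WT arrays, unchanged groups would give a lower r and covariance. The observed covariance exceeded the simulated one although the equal spread made the latter too high. The simulated genes also varied independently, which real genes do not, so the simulated range is too narrow to bound chance. Whether HET and KO changed alike thus stays open. Genes are not independent replicates.

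The comparison of KO with HET asks what the loss of the remaining allele adds. Hgf fell by 2.13 on the log2 scale (SE 0.12), Mt2 by 1.78 (SE 0.11), Luzp2 by 1.68 (SE 0.17) and Pdk4 by 1.46 (SE 0.087), with limma adjusted p of 6.0e-05 for Hgf (n = 3). Gja1 fell by 1.35 (SE 0.21), and Iqcg and Rsph4a, of which only Rsph4a is in the cilia list, both fell by 1.19 (SE 0.19). Moxd1 rose by 1.75 (SE 0.23), Pdzrn3 by 1.16 (SE 0.13) and Ptx3 by 1.10 (SE 0.10). In all, 41 genes changed, 9 upward and 32 downward, with 3 and 12 by at least 2-fold.

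The further falls were Papss2 at -1.04, Htra1, a secreted serine protease, at -1.03, Clu at -1.02 and Fam107a at -0.96. The further rises were F5 at 0.99 (from a HET mean of 4.32, again below the lower quartile of every array), Igfbp5, a binder of insulin-like growth factors, at 0.94, Has2 at 0.88, Nid1, a basement membrane protein, at 0.66, Arsb, a lysosomal sulfatase, at 0.53 and Lrig1, a restrainer of growth factor receptors, at 0.52. Prdm16 lay at -1.02 (SE 0.18, limma adjusted p = 0.078). Of the 41 genes, 37 were also called against WT, all in the same direction; the others were Gja1, Rsph4a, Kcnk1 and Dcdc2a, the last pair named after their values were seen. Both comparisons use the KO arrays: simulated unchanged groups gave at most 1 shared call, and independent lists would give 0.0149 upward and 0.0915 downward, against 9 and 28. The simulated groups had the same spread in all genotypes, while the real KO arrays varied most, so the simulated number may be too low. Neither reference number allows for a change in KO, which enters both comparisons where HET lies near WT. The overlap is thus not independent support for either set of calls.

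All 41 calls had groups that did not overlap, as did 6.54% of all genes, where chance gives 10%. After quantile normalization 16 genes rose and 34 fell, and after median centring 7 rose and 14 fell. The count was 8 with only the KO and HET arrays in the fit. It was 19, 22 or 24 without WT replicate 1, 2 or 3, 75, 12 or 19 without HET replicate 1, 2 or 3, and 27, 19 or 19 without KO replicate 1, 2 or 3.

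With 1 array left out, Pdzrn3 (highest adjusted p over all settings 0.072) and Has2 (0.11) lost the call without HET replicate 2, and Htra1 (0.14) without HET replicate 2 or KO replicate 2. Moxd1 (0.16) lost it without HET replicate 2 or 3 or KO replicate 2, Nid1 (0.14) without HET replicate 2 or 3 or KO replicate 1, and Igfbp5 (0.14) without HET replicate 3 or KO replicate 1 or 3. Clu (0.14) lost it without WT replicate 1, HET replicate 2 or KO replicate 2 or 3. Gja1 (0.285) lost it without any 1 of the 9 arrays, Iqcg (0.30) and Rsph4a (0.32) without any 1 but KO replicate 1, Arsb (0.32) without any 1 but KO replicate 2, Lrig1 (0.20) without any 1 but HET replicate 1 and Mgst1 (0.25) without any 1 but WT replicate 3. Luzp2 (0.0503), Papss2 (0.0503), F5 (0.0615) and Apoe (0.0721) lost it with only the KO and HET arrays in the fit, and Apoe also without HET replicate 1 and KO replicate 2 together.

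Against HET, 4 lists shifted downward in KO by camera. Astrocyte genes had a median of -0.18 (adjusted p = 5.2e-06; adjusted p = 0.30 with an estimated correlation), with 3 falls over all genes, Gja1, Apoe and Clu, and 7 adjusted over the list alone. Cilia genes had a median of -0.15 (adjusted p = 3.4e-07; adjusted p = 0.30 with an estimated correlation), with 1 fall over all genes, Rsph4a, and 2 adjusted over the list alone. Oxidative stress defence had a median of -0.05 (adjusted p = 0.030; adjusted p = 0.69 with an estimated correlation), with 1 fall over all genes, Mgst1, and 2 adjusted over the list alone. Oxidative phosphorylation had a median of -0.09 (adjusted p = 0.013; adjusted p = 0.78 with an estimated correlation), with 0 calls either way by limma and a higher level in HET than in WT. The oxidative stress and oxidative phosphorylation calls were lost without HET replicate 2 (adjusted p = 0.23 and 0.24), HET replicate 3 (0.069 and 0.40), KO replicate 1 (0.11 and 0.057), KO replicate 2 (0.14 and 0.89) or with quantile normalization (0.068 and 0.065), where the ventral forebrain and cell cycle lists passed instead. The oxidative stress call was also lost with the dimmest 1 in 3 genes left out (adjusted p = 0.16).

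Lists that passed against HET only in other settings were led by the ventral forebrain list, upward in 8 of them: array weights (adjusted p = 0.032), the dimmest 1 in 3 genes left out (0.039), quantile normalization (0.025), and without WT replicate 2 (0.046), WT replicate 3 (0.047), HET replicate 2 (0.028), KO replicate 2 (0.021) or HET replicate 1 and KO replicate 2 (0.024). The cell cycle list passed upward with the dimmest genes left out (adjusted p = 0.039), quantile normalization (0.025), and without HET replicate 2 (0.00032), KO replicate 1 (6.3e-05), KO replicate 2 (0.0062) or HET replicate 1 and KO replicate 2 (0.024). Downward passed meninges and fibroblasts without HET replicate 2 (adjusted p = 0.028) or KO replicate 2 (0.021), radial glia without HET replicate 3 (0.019), and postmitotic neurons without HET replicate 1 (0.0035) or HET replicate 1 and KO replicate 2 (0.013).

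KO against the mean of WT and HET, which sets cells without a wild-type allele against the others, gave 99 changed genes, 33 upward and 66 downward. These genes need not be particular to KO. Simulated genes with HET at the midpoint and a KO change of 1 on the log2 scale were called in it in 92.4% of cases. Hgf changed by -2.38 on the log2 scale (SE 0.10) and Prdm16 by -1.20 (SE 0.16, limma adjusted p = 0.0076). This count fell to between 48 and 65 without KO replicate 3 (48), WT replicate 1 (51), KO replicate 1 (53), WT replicate 2 (60), WT replicate 3 (62) or HET replicate 2 (65).

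The slope on the number of wild-type alleles fits a straight line, but genes with uneven steps can pass it too. Hgf lay at -0.50 in HET against WT and at -2.13 in KO against HET on the log2 scale. Along the slope 48 genes changed, 27 higher with more alleles and 21 lower. Hgf changed by 1.32 log2 units per allele (SE 0.15), Luzp2 by 1.07 (SE 0.13), Prdm16 by 0.69 (SE 0.10) and Ccdc190 by 0.61 (SE 0.043), and Ptx3 by -0.71 (SE 0.084) and Gatm by -0.70 (SE 0.083). The count was 10, 23 and 38 without WT replicate 1, 2 and 3, 14, 26 and 15 without KO replicate 1, 2 and 3, and 1 without HET replicate 1 and KO replicate 2 together. For HET against the midpoint of WT and KO, 952 of 19938 genes had an unadjusted p under 0.05, fewer than chance gives. No gene had HET away from this midpoint by limma with Benjamini-Hochberg, and the smallest adjusted p, 0.080, was that of Mt2. Fits with array weights, with quantile normalization, without KO replicate 3 or without HET replicate 1 gave 1, 1, 1 and 3 such genes.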

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

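The tests of a lower share of ventricular zone cells, of a larger share of ventral forebrain cells or interneurons and with the Xist covariate were chosen only after the result was seen, as was the interneuron list after the rise of Sst, Npy and Lhx6.

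Probe sets outside the comparisons of the report, those with several gene symbols or none, held a signal. A fit over every probe set called 7 of the 7151 such probe sets in KO against WT, 3 higher and 4 lower. The same fit called 3 in KO against HET and 0 in HET against WT by limma. None of the 7 is listed in the annotation used here, so they carry no gene name. The largest change was -2.61 on the log2 scale (SE 0.23, adjusted p = 0.0017 by limma with Benjamini-Hochberg, n = 3).

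The first pattern weighed was the set of 90 genes that changed in KO against WT. Genes carried along beside the targeted allele would crowd next to Prdm16, but 2 of the 153 nearest tested genes, Draxin and Fbxo2, were called, which argues against this as the source of most calls. With the Xist level as a covariate the median called gene kept 101% of its change (89.7% to 114%), and 66 of the 90 stayed called. WT replicate 1 and KO replicate 2 paired high Xist (10.04 and 10.50) with the Y-linked Eif2s3y at 8.47 and 6.85. Arrays with higher Xist tended to have lower Eif2s3y, but the levels were not in proportion. WT replicate 1 lay close to KO replicate 3 in Xist (11.002 there). Its Eif2s3y lay far from the 4.36 of KO replicate 3 and near the 8.70 of WT replicate 3. A straight-line term in the Xist level treats WT replicate 1 much like KO replicate 3. The covariate thus cannot settle what part the mixed sex of the arrays had. The 10 splits of the 6 arrays are too few for a share under 0.05: the real split gave 90 genes, reached by 1 split, and the highest other gave 0. The labels name no litter or handling batch, so none was tested, and genotype stays the difference that the design names.

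The next pattern was the lower level of astrocyte and cilia genes in KO. Without KO replicate 2 the medians were -0.347 and -0.256, which argues against that array alone as the source. If the KO samples held a lower share of ventricular zone cells, radial glia genes were predicted to fall as much. The cilia median lay 0.13 below theirs (95% bootstrap bounds of the difference -0.284 and -0.0262). For astrocyte genes the difference was -0.23 with bounds of -0.649 and 0.139. The bootstrap drew genes as if independent and held no spread between arrays, so the bounds are too narrow. A lower share of these cells could thus still contribute to the fall of both lists. Lower expression per cell and fewer glial or ciliated cells stay open and were not tested apart.

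The last pattern was the rise of the interneuron peptides Sst and Npy. A larger share of ventral forebrain cells was predicted to raise the ventral forebrain list by about as much. Its median was 0.0564 (95% bootstrap bounds -0.0133 and 0.198, all 16 genes above the floor), and 0.104 without KO replicate 2. This argues against a rise of the list by as much as Sst and Npy. The bounds hold the spread between genes but not between arrays, so a smaller rise stays open. A list of 21 measured genes, written for interneurons of the medial ganglionic eminence but holding Vip, Calb2, Cck and Reln, which mainly mark other cells, shifted up (camera p = 7.9e-06; p = 0.0097 with an estimated correlation; without Lhx6, whose value had been seen, and Reln, 7.2e-05 and 0.021), with 18 higher and 0 passing over all genes by limma. Its median of 0.239 (0.036 to 0.416) also lay below the 0.5 set for the ventral list, but 5 members, with Vip, Calb2 and Cck among them, were at the floor, and the other 16 had a median of 0.325 (0.0386 to 0.567). A larger share of interneurons thus stays open, as does more expression in them, and the list could not tell interneurons of that eminence from others.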

How the results depend on the processing

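Tests with the Xist level as a covariate and without HET replicate 1 and KO replicate 2 were chosen after the data were seen; the others were planned. The named called genes kept their sign in the settings run, and HET against WT gave 0 genes by limma in each. Of 39 named genes called in KO against WT, 14 stayed called in the settings run for them: Hgf, Pdk4, Mt2, Luzp2, Ptx3, Has2, Pdzrn3, Papss2, Ccdc190, Fam171b, Plagl1, Arsb and Fam107a in 19, and F5 in 18, since it is among the dimmest 1 in 3 genes. Of 24 called in KO against HET, 5 did, in 19 settings each: Hgf, Ptx3, Mt2, Pdk4 and Fam107a. Sst lost its call without 8 of the 9 arrays, one at a time, and Cacna2d1 without each of the 9. KO against WT counts moved to 33 with only the arrays compared, 151 with array weights and 50 without HET replicate 1 and KO replicate 2; over single arrays left out they ran from 23 to 77. KO against HET moved to 8 with only the arrays compared, 26 over every probe set, 21 with median centring and 24 with the Xist covariate, and ran from 12 to 75. KO against WT and HET ran from 48 to 102. Slope counts moved to 97 with array weights, 82 with quantile normalization, 91 at an adjusted p under 0.10, 17 at 1.5-fold or more and 1 without HET replicate 1 and KO replicate 2, and ran from 10 to 47. Genes away from the midpoint moved to 1 with array weights, quantile normalization or an adjusted p under 0.10 and 2 without HET replicate 1 and KO replicate 2, and ran from 0 to 3. Lists in KO against WT moved to 0 with an estimated correlation and 2 by fry, and ran from 2 to 6. Lists in HET against WT moved to 4 with quantile normalization and 0 with an estimated correlation or fry, and ran from 1 to 4. Lists in KO against HET moved to 0 with an estimated correlation or fry and 7 without HET replicate 1 and KO replicate 2, and ran from 3 to 5. The KO and HET correlation ran from 0.311 to 0.487. Fits with fewer arrays have fewer degrees of freedom; the cause of the other shifts was not tested. As a replicate block, the number in the titles gave 72 genes in KO against WT, 19 in KO against HET, 82 in KO against WT and HET and 30 for the slope, and changed no list count. Counts do not say which lists: the oxidative stress call was lost with the dimmest 1 in 3 genes left out in KO against WT and KO against HET, and quantile normalization lost the cilia call in HET against WT and the oxidative stress and oxidative phosphorylation calls in KO against HET. Same-numbered arrays did not deviate together: their residuals correlated between -0.336 and 0.0555 over 9 pairs. Some arrays of different number in 2 genotypes did, with 7 of 18 pairs over 0.1. The highest was HET replicate 1 with KO replicate 2, at 0.308. A factor shared by such arrays was not tested. No signal over background was given per probe set, so changes from or to a level near the floor have no bound on that level. Among others this holds for F5 in WT and HET and for Hgf and Iqcg in KO.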

Other observations

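The glucocorticoid tests, with and without the called genes, and the Xist covariate were chosen only after the fall of those genes or the sex-linked values were seen.

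Further genes called in KO against WT were chosen here after their values were seen, and no list or group of them was tested. Iqcg changed by -1.24 on the log2 scale, Lrrc9 by -1.22, Nme5 by -1.01, Lrriq1 by -0.78 and Kif27, a kinesin, by -0.72, with limma adjusted p of 0.020, 0.047, 0.039, 0.044 and 0.018 (n = 3). The call of Iqcg was lost without any 1 WT array, HET replicate 2 or KO replicate 2 or 3, with a highest adjusted p of 0.149 over its settings. Slco1c1, a thyroid hormone transporter, fell by 1.17, Fxyd1, a regulator of the sodium pump, by 1.09 and Slc7a11, the cystine and glutamate exchanger, by 0.95.

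Hapln1, which links hyaluronan to proteoglycans, fell by 0.75 and Lama2, a laminin chain, by 0.67, while Has2 rose by 1.18 and Nid1 by 0.64. The glutamate receptor genes Gria1 and Grin3a rose by 0.77 and 0.76; the calls of Gria1 and Nid1 were lost without WT replicate 1 or 2, with highest adjusted p of 0.0644 and 0.0757. These genes too were picked from the calls, so they say nothing of other matrix or receptor genes.

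Mt1, Mt2, Pdk4 and Fam107a, which respond to glucocorticoids, fell together in KO, so lower glucocorticoid signalling was tested as a hypothesis. The other 20 genes of a glucocorticoid list had a median of 0.0415 (95% bootstrap bounds -0.0156 and 0.140), with 13 of them higher. Without KO replicate 2 their median was -0.0256, so its sign rests on that array. The camera test of limma gave an adjusted p = 0.306 over the 2 lists added after the first results, this one and that of the interneurons. That list had left out the called genes; with them the median of 24 genes was 0.0155 and its bounds, -0.133 and 0.0904, reached below the -0.1 set for a shift. A part for glucocorticoids in the fall of these 4 genes thus could neither be shown nor excluded.

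Other splits of the arrays were counted for each result. For KO against HET 10 splits are too few for a share under 0.05, with 41 genes in the real split, reached by 1, and 0 at most in the others. For HET against WT they are too few too, with 0 genes by limma in all 10. In the real split 808 of 19938 genes had an unadjusted p under 0.05, fewer than chance gives. Lists had 4 in the real split and 4 at most in others for KO against WT, 2 and 5 for HET against WT, and 4 and 6 for KO against HET. These real counts were reached by 3, 8 and 3 of the 10 splits. In each comparison regrouped arrays thus gave as many lists or more, so the number of lists called does not set the genotypes apart. The count takes no account of which lists passed or how strongly. For KO against the other arrays in a fit of 2 groups, 1 of 84 splits, the real one, gave 90 genes and the highest other 3. For the slope 1 of 100 splits, the real one, gave 48 genes and the highest other 0. Both shares lie under 0.05, so a chance labelling of the arrays would rarely give as many. Since the arrays of a genotype may not be separate animals, a chance difference between litters or pools is not covered. For HET against the midpoint the real split gave 0 genes, so 100 of 100 splits gave as many. The highest other gave 76, with the KO arrays as the middle group between mixed groups of WT and HET arrays. That split thus sets KO against the other arrays, a difference already reported.

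Sex-linked genes differed between arrays of 1 genotype. Xist was 10.04, 4.44 and 4.70 in WT, 10.73, 4.64 and 4.99 in HET and 4.42, 10.50 and 11.002 in KO. Eif2s3y was 8.47, 8.98 and 8.70 in WT, 4.03, 9.13 and 8.99 in HET and 9.19, 6.85 and 4.36 in KO. WT replicate 1 and KO replicate 2 had high values of both, as RNA pooled from pups of both sexes would give, so these arrays may be pools and n may count pools rather than pups. Pooling was not tested; with the Xist level as a covariate the median called gene of KO against WT kept 101% of its change.

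Genes with 1 identical value in all 3 arrays of a genotype numbered 682 in WT, 359 in HET and 298 in KO. Of these, 1 was called, Draxin, with identical values in HET.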
